A study of Mus musculus with 4 samples.

How the data were processed

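Total RNA from the 4 macrophage samples was labelled with biotin and hybridised to a mouse Affymetrix expression array with 45037 probe sets and 64 controls, per the labels' protocols and the deposited table. The deposited values are intensities, 1 linear signal per probe set and array, made by the authors with MAS 5.0, per the submitters' processing notes. MAS 5.0 combines the perfect match and mismatch probes of a probe set into 1 signal and scales each array as a whole. In the deposited intensities the mean without the lowest and highest 2% of probe sets was 500 on all 4 arrays, so that scaling was kept and nothing was done between arrays. This scaling makes the arrays equal in their mean, which bright probe sets dominate, and leaves differences at low signals, where fold changes are the least certain. The table used here holds no detection calls. Replicates were not pooled. No pair of arrays shared more than 74 identical values, so no array was a copy of another. The labels give a priming time of 16 h for the LPS group and say overnight for the other.

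Groups and replicate numbers were taken from the sample titles. Signals were transformed to log2(signal + 32), which understates the change of dim probe sets. The 64 control probe sets and probe sets with a mean signal over the 4 arrays under the 40th percentile were left out, which left 27022 with a mean of at least 69.7. LPS plus immune complexes was compared with LPS in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, a trend of the variance with the mean, no block and a two-sided moderated test. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called, and every adjusted p for a gene or probe set is from this fit. The fitted prior had 9.87 degrees of freedom. Fold changes are means of log2 values over 2 arrays, given with limma's standard error. Signals are given as mean ± SD of 2 arrays or as the readings of single arrays. A separate count, without a test, took probe sets that differed by at least 2-fold in the same direction in all 4 pairs of an array of each group.

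Gene names came from GEO's annotation of the array, of which 34945 probe sets name 1 gene, 932 several and 9160 none. Gene IDs of 34741 probe sets with 1 gene matched NCBI RefSeq's gene table of GRCm38.p6, and no symbol differed from it. Probe sets with several genes or none were tested and left unnamed as genes. No position in the genome is given, since the array's annotation names no build. Each of the 12891 tested genes took its tested probe set with the highest mean signal, and other probe sets of a gene are mentioned where they passed.

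Before the data were examined, 34 gene lists, the tests and the alternatives were fixed. A list with at least 3 tested members was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists tested. The same test with a correlation estimated per list, and fry, which asks whether a list's own genes move, on balance, in 1 direction, were alternatives. Of 498 listed names 454 matched a gene on the array. The rule for naming genes was also fixed in advance. It took (a) up to 12 genes with the largest rises and falls among those past the threshold and moved in the same direction in all 4 pairs, filled to 12 from the 2-fold count where fewer than 5 passed in a direction, (b) every macrophage activation marker, (c) up to 4 members of each list described, those past the threshold first and then by size, and (d) all of a count of 5 or fewer.

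Every result was recomputed with quantile normalization or median centring over the tested probe sets, with a pseudocount of 1 or 100, without a filter or with the 60th percentile as filter, without the variance trend, with the replicate number as a block, and without each array in turn. Where 1 array stands for a group, it is assumed to vary like the other group's arrays. Counts were also taken at adjusted p under 0.1, at 3-fold, with the mean over a gene's probe sets, and without probe sets whose ID ends in _x_at or _s_at, which can bind transcripts of several genes. A filter at a mean signal of 500, and quantile normalization with the replicate block, were added after the data had been seen.

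The method was tested on 60 simulated data sets of 27022 probe sets with the means and fitted spread of these arrays and 200 probe sets changed for LPS plus immune complexes against LPS. It called 0.1% of probe sets changed by 1 on the log2 scale, 10.3% of those changed by 2 and 40.6% of those changed by 3. Of all calls 7.3% were false, above the nominal 5%, and the number of data sets had been raised to 60 after a first run with fewer had shown a share above it. No call had the wrong sign. With no change it made 0.15 calls per data set. The 25 tested immediate early genes, shifted by 0.6, were called as a list in all 60, and without a shift 5 lists were called over all data sets. Simulated probe sets varied independently, which real genes of a list need not do, and their spread came from the fit without a block. Figures were drawn with matplotlib.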

Results

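Transcript levels were measured in mouse macrophages grown from bone marrow in medium with 20% L-cell conditioned medium, a source of the growth factor M-CSF, for 7 days. The cells were primed overnight with interferon-gamma at 100 U/ml, washed, and stimulated for 2 h in either of 2 ways. The LPS group received lipopolysaccharide (LPS, a bacterial cell wall component that engages TLR4) at 10 ng/ml, a treatment that the series calls classical activation. The other group received the same dose of LPS together with immune complexes, antibody bound to antigen that engages Fc gamma receptors, which the series calls type II activation. Each group had 2 arrays, labelled replicate 1 and replicate 2, and each array gave MAS 5.0 signals for 45037 probe sets besides 64 controls. The labels do not state that replicates came from separate cultures or animals, so p-values here measure the spread between these samples, which may be technical.

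The arrays had the same trimmed mean signal of 500 but not the same distribution. The median signal was 88.6 and 79.8 on the LPS arrays, and 155.8 and 68.4 on the LPS plus immune complexes arrays of replicates 1 and 2. The 5th percentile was 28.1 on the first LPS plus immune complexes array against 3.3 to 7.9 on the other 3 arrays. Across the 27022 tested probe sets, Pearson's r was 0.93 between the LPS arrays and 0.89 between the LPS plus immune complexes arrays. Arrays with the same replicate number and different stimulation had r of 0.91 for replicate 1 and 0.97 for replicate 2. Arrays that shared neither had r of 0.93 for LPS replicate 1 with LPS_IC replicate 2 and 0.87 for LPS replicate 2 with LPS_IC replicate 1, so the arrays grouped neither by stimulation nor by replicate number throughout. Probe sets are not independent replicates in these correlations. The first principal component held 62.2% of the variance and set the first LPS plus immune complexes array apart, and the third, with 13.6%, separated the stimulations within replicate 2. The 3' to 5' signal ratio of the Gapdh controls, a measure of RNA integrity, lay between 0.77 and 1.12, and that of the actin controls between 1.21 and 1.3.

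The series asks which genes mark macrophages given LPS with immune complexes as opposed to LPS alone. Adding immune complexes raised 8 genes past the threshold, each between 5.29-fold and 10.8-fold and each at least 2-fold higher in all 4 pairs of arrays. Hbegf, a heparin-binding growth factor of the EGF family, rose from a signal of 818.9 ± 244.5 to 6601 ± 814 (SD, n = 2 arrays per group), a log2 fold change of 2.99 ± 0.36 (SE). The limma adjusted p was 0.0236 for Hbegf, and its other probe set rose too, by 2.84 on the log2 scale. Tent5c, a non-canonical poly(A) polymerase, rose by 3.02 ± 0.35, and a separate Tent5c probe set by 3.18, both with limma adjusted p = 0.0236. Lhfpl2, a tetraspan membrane protein, went from 352.2 ± 38.7 to 3061.6 ± 92.6, a log2 fold change of 3.01 ± 0.37. Fabp4, a fatty acid-binding protein of adipocytes and macrophages, rose 6.59-fold, from 783.6 ± 328.5 to 5134.4 ± 481.5. Tmem267 had the highest log2 fold change, 3.43 ± 0.45, followed by Cgref1, an EF-hand protein, at 3.30 ± 0.47, and both were low on the LPS arrays, with mean signals of 91.1 and 81.9. Cipc, a repressor that binds the circadian factor CLOCK, rose 6.08-fold, and Gas2l3, a linker of actin and microtubules, 5.29-fold, each with limma adjusted p = 0.0479.

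By probe set, 12 were higher and 2 lower with immune complexes. Besides the genes above, the higher probe sets included a dimmer Eif4e probe set, which rose by 2.67, while the brightest probe set of Eif4e, the cap-binding translation factor, had a log2 fold change of 0.80 ± 0.31 with adjusted p = 1. Another named no gene and rose 8.8-fold. The lower probe sets were a dimmer one of Il12b, the subunit shared by IL-12 and IL-23, and one annotated to both Il4i1 and Il4i1b. The latter, which stands for no single gene here, fell from 2490.9 ± 538.2 to 350.6 ± 119.5. Its log2 fold change was -2.74 ± 0.41 with limma adjusted p = 0.0479. The dimmer Il12b probe set fell from 2177.4 ± 230.4 to 293.6 ± 42.4, a log2 fold change of -2.76 ± 0.39 with limma adjusted p = 0.0367. The brighter Il12b probe set, which stands for the gene, had -2.05 ± 0.48 with adjusted p = 0.284 and LPS readings of 1574.7 and 3789.8, so Il12b counted as not passing. No gene passed on the lower side by its brightest probe set in this fit without a block. At an unadjusted limma p under 0.05, 256 probe sets were lower, against 503 higher. With the replicate number as a block, limma called 224 genes higher and 167 lower. The prior degrees of freedom were infinite in that blocked fit, so a probe set's own spread did not count.

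**Figure D1:**
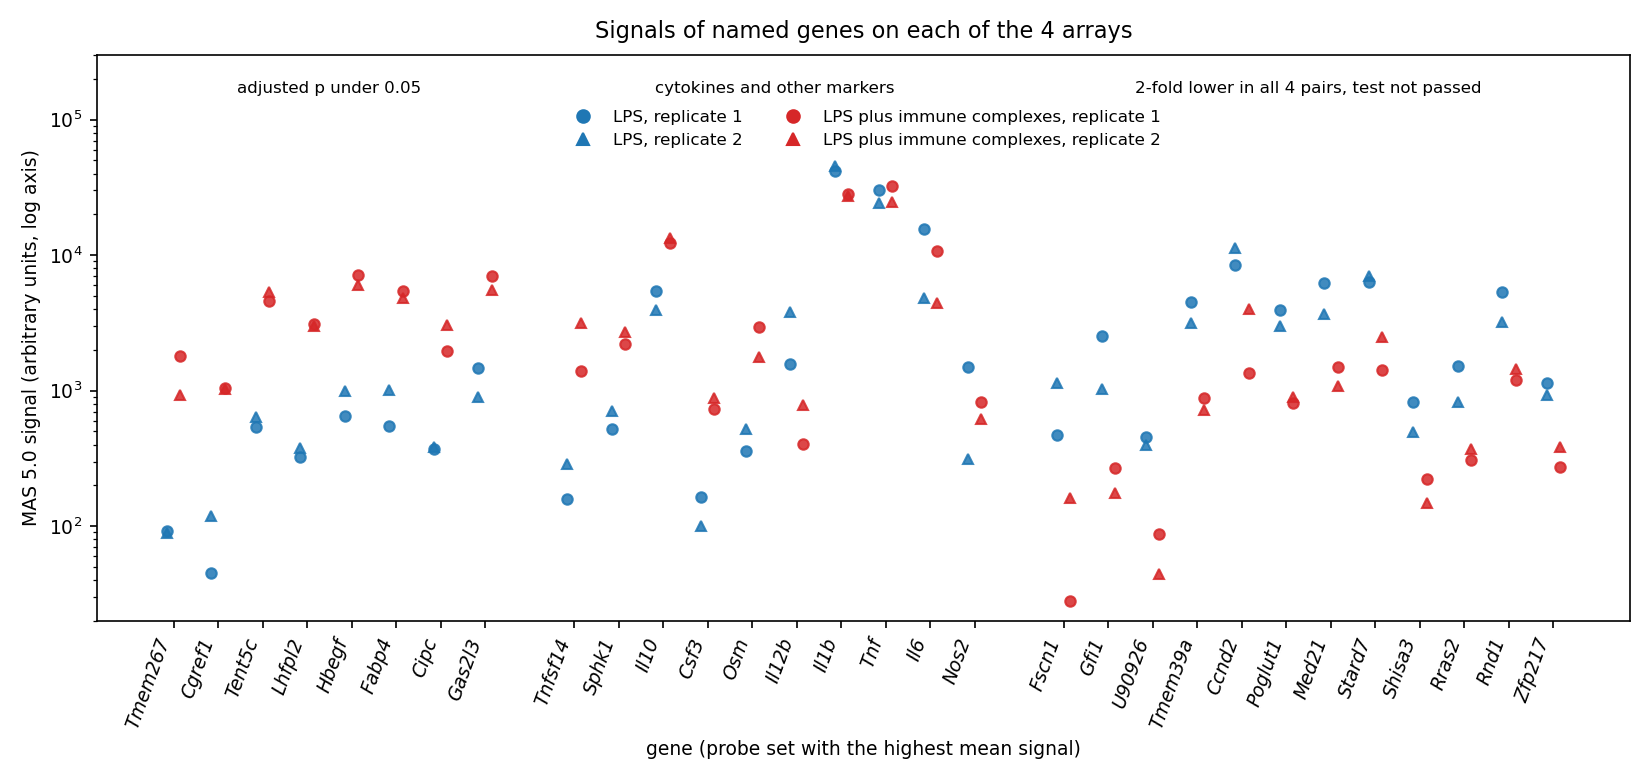
MAS 5.0 signal (log axis) of named genes on each array, with LPS in blue and LPS plus immune complexes in red, circles for replicate 1 and triangles for replicate 2. The 8 genes that passed the test are at the left, cytokines and other markers in the middle, and at the right the 12 genes with the largest decreases that were at least 2-fold in all 4 array pairs without passing. Hbegf reads 646 and 991.8 with LPS against 7176.5 and 6025.4 with immune complexes, while Tnf lies between 24355.5 and 32133.4 on all 4 arrays.

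Since fewer than 5 genes passed on the lower side, the 12 with the largest decreases among those at least 2-fold lower in all 4 array pairs are named here. None of them passed in the fit without a block. Fscn1, an actin-bundling protein, had a log2 fold change of -2.83 ± 0.61, and Gfi1, a transcriptional repressor of myeloid cells, one of -2.72 ± 0.48 with signals of 1774.1 ± 1053.4 and 221.7 ± 66.2. Their limma adjusted p-values were 0.223 and 0.0945. Ccnd2, which encodes cyclin D2, read 8403.6 and 11203.5 with LPS and 1350.3 and 3982.9 with immune complexes. The small GTPases Rras2 and Rnd1 had log2 fold changes of -1.64 ± 0.43 and -1.63 ± 0.37. The others were U90926, Tmem39a, Poglut1, Med21, Stard7, Shisa3 and Zfp217, with log2 fold changes from -2.26 to -1.57 and adjusted p from 0.072 to 0.562. Over all genes, 101 were at least 2-fold higher and 24 at least 2-fold lower in all 4 pairs, and 204 and 50 probe sets. The balance of directions depended on 1 array: without LPS_IC replicate 1, the array with raised low signals, 315 probe sets were higher and 700 lower, while the counts were 3994 and 523 without LPS_IC replicate 2, 782 and 154 without LPS replicate 1, and 894 and 278 without LPS replicate 2, each over 2 array pairs. This fold count carries no test. It took 254 probe sets, against 1109 for the split of the arrays by replicate number and 139 for the crossed split, which sets LPS replicate 1 and LPS_IC replicate 2 against the other arrays. Among probe sets with a mean signal of 500 or more the counts were 130 for the stimulations, 284 for the replicate numbers and 1 for the crossed split, whose sides each mix both stimulations and both numbers. In data simulated without any change a mean of 584.3 probe sets met it, but that simulation took its spread from the fit without a block, so differences shared by replicate numbers entered it as independent spread. All 14 probe sets that passed the test also met it.

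**Figure D2:**
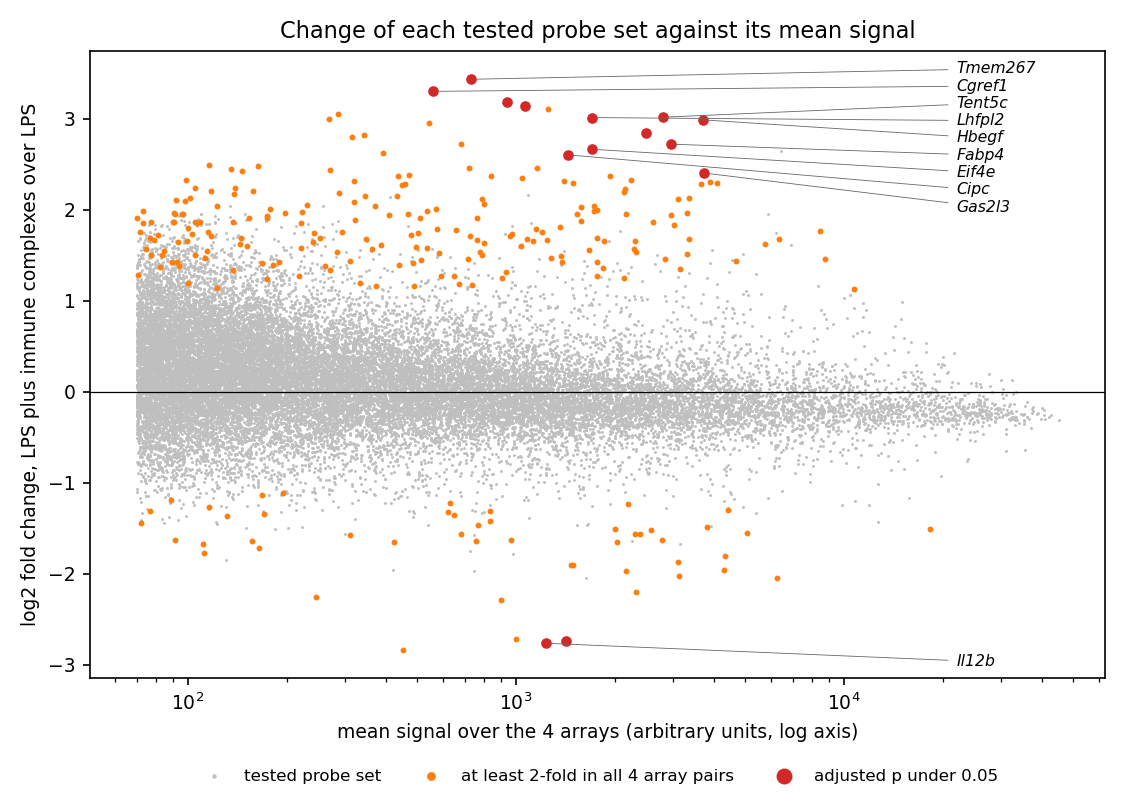
Log2 fold change of LPS plus immune complexes over LPS for each of the 27022 tested probe sets (vertical axis) against its mean signal over the 4 arrays (horizontal log axis). Red points are the 14 probe sets with adjusted p under 0.05, labelled once per gene where 1 gene is named, and orange and red points together those at least 2-fold different in all 4 array pairs, 204 higher and 50 lower. Most probe sets at the right, with the highest signals, lie a little below 0, as the reference genes do with a median of -0.22, which is -0.02 with quantile normalization.

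Among 16 markers of macrophage activation fixed in advance, 13 were bright enough to test, and 1, Hbegf, passed over all probe sets. Adjusted over the list alone, 4 were higher and 2 lower. The higher ones were Hbegf, Tnfsf14 (LIGHT, a TNF family ligand), Sphk1 (sphingosine kinase) and Il10, the anti-inflammatory cytokine. Il10 read 5474.4 and 3904.7 with LPS and 12288.3 and 13346.9 with immune complexes, a log2 fold change of 1.46 ± 0.29 with adjusted p = 0.164. Tnfsf14 had 3.11 ± 0.48 with adjusted p = 0.0546, and Sphk1 had 1.95 ± 0.38 with adjusted p = 0.137. The lower ones were Il12b and Il1b, the latter at -0.64 ± 0.21. Signals of the inflammatory cytokine Tnf differed by a log2 fold change of 0.06 ± 0.24, those of Il6 by -0.33 ± 0.51, of Nos2, the inducible nitric oxide synthase, by 0.04 ± 0.59, of Dusp1 by -0.12 ± 0.23, of Cd86 by 0.31 ± 0.43, of Cd40 by -0.46 ± 0.24 and of Il12a by -0.69 ± 0.68, none past the threshold. Arg1, Retnla and Ccl1 lay below the filter on signal, with no reading above 129. As a list the 13 tested markers were not past the threshold (camera adjusted p = 0.0972, and 0.561 with an estimated correlation). With quantile normalization the list was higher (camera adjusted p = 0.0246).

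The shorter list of markers reported for such cells, Il10, Sphk1, Tnfsf14, Hbegf and Ccl1, was higher as a set, with a median log2 fold change of 2.47 over 4 tested members and a camera adjusted p of 3.41e-18. With an estimated correlation its adjusted p = 0.38. All 4 were at least 2-fold higher in all 4 array pairs, and all 4 passed when adjusted over the list alone. The laboratory that made these arrays reported some of these genes from such cells, so neither this list nor the marker list above is independent evidence of its direction.

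The 15 tested pro-inflammatory cytokines were lower as a list (median log2 fold change -0.53, camera adjusted p = 0.0216; adjusted p = 0.561 with an estimated correlation), though their mean was -0.16 because members lay on both sides. None passed over all probe sets. Adjusted over the list alone, 4 were lower, namely Il12b, Ebi3 (a subunit of IL-27 and IL-35, -1.13 ± 0.36), Il15 (-0.82 ± 0.30) and Il1b, and 2 were higher. These were Csf3, the growth factor G-CSF, at 2.38 ± 0.44 with adjusted p = 0.103, and Osm, oncostatin M, at 2.31 ± 0.41 with adjusted p = 0.0945. Il23a read 246.2 and 268.6 with LPS and 289.5 and 21.8 with immune complexes. The list lost its call with quantile normalization (median -0.38, adjusted p = 0.164), with median centring (0.0879), without limma's variance trend (0.126) and without LPS replicate 1 (median -0.2, 0.477) or LPS_IC replicate 2 (median -0.05, 0.353), the second LPS plus immune complexes array. The 22 tested chemokines were not past the threshold as a list (median -0.06, camera adjusted p = 0.491). Only Ccl2, a monocyte attractant, passed among them when adjusted over the list alone, at 1.16 ± 0.28, and Cxcl13 and Cxcl11 had 1.37 ± 0.94 and -1.20 ± 0.43. Cxcl13 read 11.5 and 86.6 with LPS and 388.9 and 50.3 with immune complexes, so it rose in replicate 1 only. Ccl7 read 1008.4 and 1663.7 with LPS and 2478.8 and 5616.6 with immune complexes, and Ccl24 read 286.4 and 316.6 against 39.9 and 161.9. The mean of the chemokines was 0.01, opposite in sign to their median.

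Immediate early genes, the transcription factors and regulators induced first after a stimulus, were higher as a list. Their median log2 fold change was 0.83 over 25 tested members, 20 of them above 0, with a camera adjusted p of 4.77e-08 and adjusted p = 0.561 with an estimated correlation. Fosl1 (1.90 ± 0.44) and Fosb (1.54 ± 0.60), partners of the AP-1 complex, and Fos (1.33 ± 0.42) lay on the higher side and Ier2 (-1.52 ± 0.35) on the lower. None of the 25 passed over all probe sets, while Fosl1 and Ier2 passed when adjusted over the list alone. The list median was 0.55 without LPS replicate 1 and 0.47 without LPS_IC replicate 1. Targets of cAMP and CREB were higher too (14 tested, median 0.45, camera adjusted p = 0.0103; adjusted p = 0.561 with an estimated correlation), led by the nuclear receptors Nr4a3 (1.10 ± 0.38), Nr4a1 (1.06 ± 0.47) and Nr4a2 (0.85 ± 0.42) and by Per1 (1.02 ± 0.68). Per1 read 34.3 and 160.2 with LPS and 274.2 and 140.3 with immune complexes, so it rose in replicate 1 only. The Nr4a genes belong to both lists. The cAMP list lost its call without LPS replicate 1 (median 0.27, adjusted p = 0.0618) and without LPS_IC replicate 2 (median 0.85, 0.282), and its median was 0.27 without LPS_IC replicate 1 and 0.25 with median centring. Feedback inhibitors of MAP kinases did not pass as a list (19 tested, median 0.23, camera adjusted p = 0.183). The phosphatases Dusp4 (1.68 ± 0.35), Dusp10 (1.56 ± 0.45) and Dusp5 (1.41 ± 0.41) passed when adjusted over that list alone, and Spry4 had -0.93 ± 0.82. Calcium and NFAT targets did not pass either (15 tested, median 0.22, camera adjusted p = 0.229), with Tnfsf14 higher and Cd69, an early activation antigen, lower at -1.55 ± 0.34 when adjusted over the list alone, and Egr2 at 1.07 ± 0.50.

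Genes of the NF-kB pathway and its feedback loop were lower as a list. Of 20 tested members 18 had log2 fold changes below 0 and 11 were lower in all 4 array pairs, with a median of -0.41, a camera adjusted p of 1.47e-08 and adjusted p = 0.561 with an estimated correlation. Birc2 (-1.24 ± 0.36) and Birc3 (-0.83 ± 0.26), inhibitors of apoptosis, Tnip1 (-0.86 ± 0.29), an inhibitor of the pathway, and Bcl3 (-0.85 ± 0.46) had the largest values, none past the threshold over all probe sets or over the list alone. With quantile normalization the list median was -0.28 with adjusted p = 0.000443. Without LPS_IC replicate 1 it was -0.19 with adjusted p = 0.0113, no lower than the reference gene median of -0.25 in the same fit.

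Several other lists were lower by small amounts, close to the shift of the reference genes. The 9 tested reference genes, including Actb (-0.30 ± 0.21), Eef1a1 (-0.25 ± 0.21), Sdha (-0.32 ± 0.34) and Tubb5 (-0.24 ± 0.41), were all below 0, with a median of -0.22 and a camera adjusted p of 0.0341 (adjusted p = 0.561 with an estimated correlation). Their median was -0.02 with quantile normalization and -0.41 with median centring (adjusted p = 0.0879), and leaving out any of the 4 arrays ended the call, with medians from -0.25 to -0.15 and adjusted p of 0.268 and 0.074 without LPS replicates 1 and 2 and of 0.157 and 0.125 without LPS_IC replicates 1 and 2. Type I interferon response genes had a median of -0.18 (26 tested, camera adjusted p = 0.0103; adjusted p = 0.631 with an estimated correlation), with Mx1 at -0.70 ± 0.32, Isg20 at -0.63 ± 0.50 and Usp18 at -0.62 ± 0.39, while Ifnb1, the interferon itself, read 1253 and 476.9 with LPS and 4574.3 and 1373.3 with immune complexes. Interferon-gamma response genes had -0.15 (22 tested, camera adjusted p = 0.0341; adjusted p = 0.631 with an estimated correlation), with Irf8 at -0.70 ± 0.29 and Cd274, the ligand PD-L1, at 0.60 ± 0.32. The interferon lists turned to medians of 0.05 and 0.03 without LPS replicate 1 (adjusted p = 0.536 and 0.582), and the interferon-gamma list to 0.01 with quantile normalization. Without LPS_IC replicate 1 their medians were -0.09 and -0.1 (adjusted p = 0.645 and 0.521), without LPS replicate 2 the interferon-gamma median was -0.3, and without LPS_IC replicate 2 it was -0.16 (adjusted p = 0.0516). IL-10 and STAT3 targets had -0.22 (15 tested, camera adjusted p = 0.00748; adjusted p = 0.631 with an estimated correlation), with the inhibitory receptor Fcgr2b at -1.28 ± 0.37 and Il10ra at -0.92 ± 0.38, and lost their call without LPS_IC replicate 1 (median -0.13, adjusted p = 0.645), with a median of -0.35 without LPS replicate 1. MHC class II genes had -0.21 (11 tested, camera adjusted p = 0.0326; adjusted p = 0.561 with an estimated correlation), with H2-DMa at -0.34 ± 0.27 and H2-Aa at -0.31 ± 0.21. Their adjusted p was 0.0686 and 0.37 without LPS replicates 1 and 2 (medians -0.31 and -0.1) and 0.432 without LPS_IC replicate 1 (median -0.14). Median centring ended the calls of the interferon-gamma and MHC class II lists (0.0879 for each). Quantile normalization ended the calls of these 5 lists, with medians of -0.02, -0.12, 0.01, -0.08 and -0.05 and adjusted p of 0.89, 0.673, 0.885, 0.367 and 0.687 in the order given. Calls also ended without limma's variance trend for the reference, interferon-gamma and MHC class II lists (adjusted p = 0.126 for each), and with the mean over a gene's probe sets for the same lists (medians -0.16, -0.06 and -0.17, adjusted p = 0.0552, 0.171 and 0.0815). The 60th percentile filter ended the calls of the reference and interferon-gamma lists (0.0521 and 0.0633), and a filter at a mean signal of 500 those of the reference, type I interferon, interferon-gamma and STAT3 lists (0.114, 0.19, 0.178 and 0.128).

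Another 3 lists were lower by similar amounts. Macrophage identity genes had a median of -0.21 (18 tested, camera adjusted p = 0.00525; adjusted p = 0.631 with an estimated correlation), with the phagocytic receptor Mertk at -1.03 ± 0.46 and the transcription factor Spi1 at -0.53 ± 0.30. Alternative activation markers had -0.21 (9 tested of 17, camera adjusted p = 0.0341; adjusted p = 0.631 with an estimated correlation), with Fn1 at -1.05 ± 0.65 and Ccl22 at 0.32 ± 0.59. Cholesterol synthesis and uptake genes had -0.30 (13 tested, camera adjusted p = 0.0342; adjusted p = 0.631 with an estimated correlation), with Fdft1 at -0.83 ± 0.40 and Hmgcs1 at -0.64 ± 0.30, and their median turned to 0.05 without LPS replicate 1 (adjusted p = 0.664). The cholesterol list also lost its call with median centring (0.0714), with the mean over a gene's probe sets (median -0.09, 0.171), with the filters at the 60th percentile and at a mean signal of 500 (0.109 for each), without limma's variance trend (0.103) and without LPS_IC replicate 1 (median -0.36, 0.146) or 2 (median 0, 0.247), and had a median of -0.46 without LPS replicate 2. The alternative activation median was -0.67 and -0.17 without LPS replicates 1 and 2 and -0.04 and -0.51 without LPS_IC replicates 1 and 2, with adjusted p of 0.00501, 0.923, 0.847 and 0.000939. This list also lost its call without a filter (median -0.05, 0.148), with the filters at the 60th percentile (0.0932) and at a mean signal of 500 (0.74), and without the variance trend (0.0541). The identity median was -0.35 and -0.11 without LPS replicates 1 and 2 and 0 and -0.34 without LPS_IC replicates 1 and 2, with adjusted p of 0.00224, 0.074, 0.728 and 0.000857, and 0.0661 with the filter at a mean signal of 500. With quantile normalization the medians of the identity, alternative activation and cholesterol lists were 0, -0.19 and -0.21, with adjusted p of 0.673, 0.244 and 0.31. None of their members passed over all probe sets or over the list alone.

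Oxidative stress response genes were higher as a list (12 tested, median 0.16, mean 0.50, camera adjusted p = 0.00595; adjusted p = 0.561 with an estimated correlation). Hmox1, heme oxygenase, read 3195.5 and 1426 with LPS and 13583.9 and 5173.6 with immune complexes, a log2 fold change of 1.96 ± 0.48. Srxn1, sulfiredoxin, had 1.43 ± 0.33, and both passed when adjusted over the list alone, as none of the list did over all probe sets. Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, had 1.33 ± 0.47 and 1.17 ± 0.43. The list median was -0.04 with median centring, 0.29 with quantile normalization and 0.55 with the mean over a gene's probe sets, which left the camera call in place (adjusted p = 0.0196, 0.000258 and 0.00138). The call was lost without limma's variance trend (0.089), without LPS replicate 2 (0.074) and without either LPS plus immune complexes array (medians 0.11 and 0.41, adjusted p = 0.153 and 0.105 without replicates 1 and 2).

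Other metabolic and effector lists did not pass with camera. Growth factors and tissue remodelling genes had a median of 0.37 (19 tested, adjusted p = 0.109), with Hbegf the gene that passed and Mmp12, a macrophage elastase, at 1.48 ± 0.46, Plau at 1.42 ± 0.66 and Mmp9 at 0.96 ± 0.92. Lipid mediator genes had -0.01 (16 tested, adjusted p = 0.531), with Sphk1 passing over the list alone and Ptges, a prostaglandin E synthase, at -1.04 ± 0.42. Hypoxia response genes had 0.29 (14 tested, adjusted p = 0.346), where Ndrg1 at 1.75 ± 0.38 passed over the list alone. Glycolysis genes had -0.08 (14 tested, adjusted p = 0.681), with the hexokinases Hk1 and Hk2 at 0.76 ± 0.38 and 0.58 ± 0.28. Cholesterol export and LXR targets had -0.16 (9 tested, adjusted p = 0.288), and heat shock and proteotoxic stress genes -0.13 (16 tested, adjusted p = 0.324), with Hspa1b at -1.09 ± 0.43. Costimulatory molecules had -0.22 (10 tested, adjusted p = 0.346), where Tnfsf14 was higher and Icosl, the ligand of ICOS, lower at -1.64 ± 0.41 over the list alone. Fc receptor signalling genes had -0.14 (17 tested, adjusted p = 0.256). The means of the costimulatory, lipid mediator and glycolysis lists were 0.05, 0.12 and 0.01, opposite in sign to their medians. Cell cycle genes had 0.25 (18 tested, adjusted p = 0.531), and they differed between replicate numbers. Top2a, a DNA topoisomerase of dividing cells chosen after its values were seen, read 401.1 and 539.4 on the replicate 1 arrays and 2512.8 and 2702.9 on the replicate 2 arrays.

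**Figure D3:**
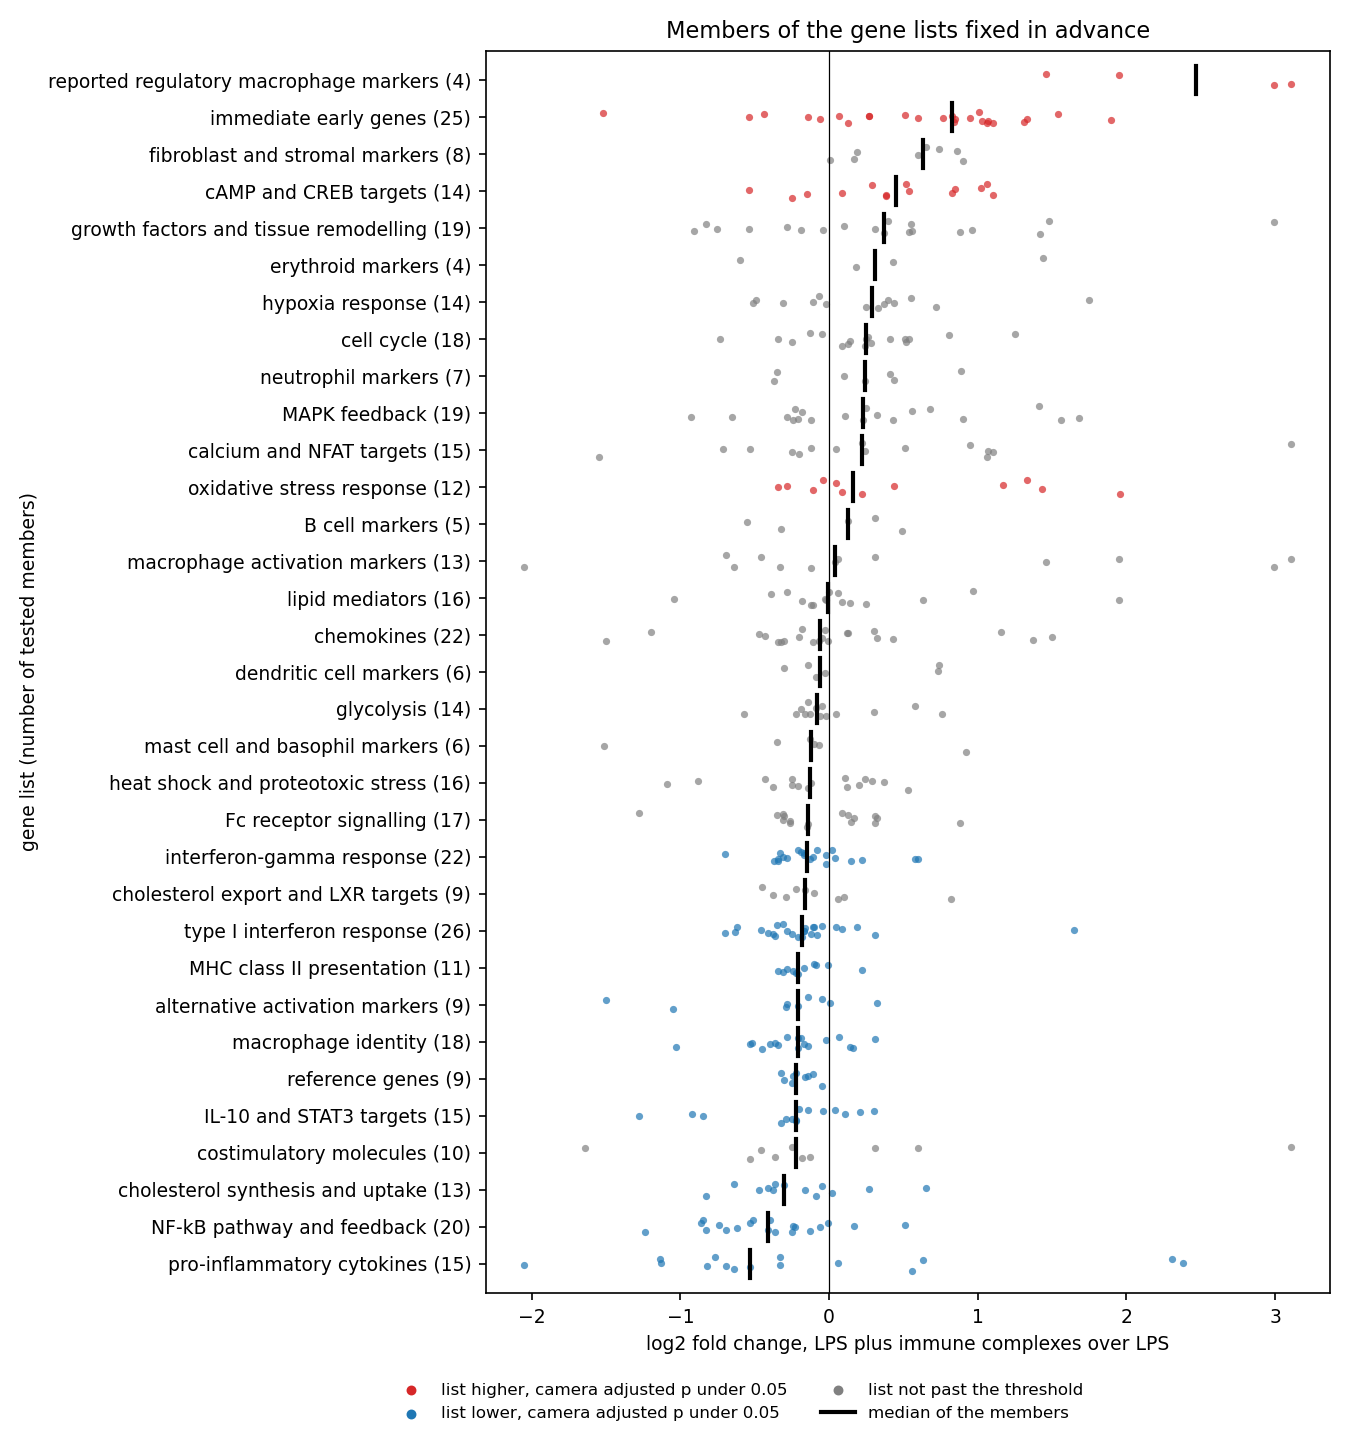
Log2 fold change of LPS plus immune complexes over LPS (horizontal axis) of each tested member of the 33 tested gene lists, ordered by median (black bars), with the number of tested members in brackets. Red lists were higher and blue lists lower with a camera adjusted p under 0.05 at a preset correlation of 0.01, and with an estimated correlation none was. Immediate early genes have a median of 0.83 and NF-kB genes one of -0.41, while the reference genes lie at -0.22.

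Markers of other cell types did not pass in any list. Medians were 0.24 for neutrophils (7 tested, camera adjusted p = 0.366), 0.13 for B cells (5 tested, 0.744), 0.31 for erythroid cells (4 tested, 0.519), 0.63 for fibroblasts and stroma (8 tested, 0.183), -0.06 for dendritic cells (6 tested, 0.973; mean 0.15) and -0.12 for mast cells and basophils (6 tested, 0.332). Of 12 T and NK cell markers only Cd8a and Cd2 were bright enough to test, too few for a list test, with log2 fold changes of 1.55 ± 0.84 and 1.07 ± 1.14. Fibroblast markers such as Pdgfra (335.8 against 51.1 to 79) and Sparc (375.4 against 46.2 to 75.1) were highest on the first LPS plus immune complexes array, the array with the raised 5th percentile of all signals. Hba-a1, a hemoglobin chain, read 246.3 there and 40.3 to 123.4 on the other arrays.

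The number of arrays limits the precision. With 2 arrays against 2, a two-sided exact permutation test of a single gene cannot go below p = 0.333, so the calls above rest on limma's spread shared across probe sets and are 14 of 27022 probe sets. Their number depended on single arrays, on scaling and on the replicate number, which as a block gave 671 probe sets, with 224 genes higher and 167 lower. Over 15 settings the log2 fold changes of the 8 genes stayed between 2.07, for Gas2l3, and 3.89, for Tmem267, and that of Hbegf between 2.69 and 3.28. These genes were picked for large changes on the same arrays, which favours such a range. Leaving out either LPS plus immune complexes array left 0 limma calls (690 and 4190 probe sets at an unadjusted p under 0.05 without replicate 1 and 2), and leaving out LPS replicate 1 or 2 gave 98 and 106. Quantile normalization gave 0 calls (823 at an unadjusted p under 0.05), as did limma without its trend of variance with signal (619). Median centring, which lowers each log2 fold change by 0.2 on average, gave 47, with 33 higher and 14 lower, and 145 higher and 86 lower probe sets in the 2-fold count. Limma's prior degrees of freedom were infinite in that fit, with the block and without either LPS array, so a probe set's own spread did not count there.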

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

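All alternatives here were fixed before the data were examined except the filter at a mean signal of 500 and quantile normalization with the replicate block. Arrays have no depth in reads. The limit is signal over background, and although the called probe sets had mean signals over 500, limma with that filter called 0, with 476 at an unadjusted p under 0.05 and a smallest adjusted p of 0.057.

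The 14 probe sets called, 8 genes called, 254 probe sets at least 2-fold different in all pairs and 14 gene lists moved as follows. Quantile normalization gave 0 probe sets, 0 genes and 6 lists, and limma without the variance trend 0, 0 and 7. Median centring gave 47 probe sets and 25 genes. Pseudocount 1 gave 23 probe sets, 13 genes and 423 probe sets by fold, and pseudocount 100 gave 6, 3 and 143. Without a filter there were 89 probe sets and 49 genes, at the 60th percentile 4 and 2, and at a mean signal of 500 there were 0, 0, 130 by fold and 8 lists. At adjusted p under 0.1 there were 37 probe sets and 22 genes, and at 3-fold 52 probe sets. With the mean over a gene's probe sets 26 genes passed, and 5 without _x_at and _s_at probe sets. With an estimated correlation 0 lists passed and with fry 0, where the smallest adjusted p was 0.38 and 0.127. Leaving out an array in turn gave 0 to 106 probe sets, 0 to 60 genes, 254 replaced by 936 to 4517 by fold, with 2 array pairs in place of 4 and from 315 higher and 700 lower without LPS_IC replicate 1 to 3994 and 523 without LPS_IC replicate 2, and 7 to 13 lists. The lists of type I interferon response, interferon-gamma response and cholesterol synthesis turned to medians of 0.05, 0.03 and 0.05 without LPS replicate 1, and had -0.25, -0.3 and -0.46 without LPS replicate 2. Of the 8 genes called, 8 passed again with median centring, with pseudocount 1, without a filter, with the replicate block, and with quantile normalization besides the block. With pseudocount 100, 3 passed, at the 60th percentile 2, and with quantile normalization alone, without the trend or at a mean signal of 500, 0. Over all 15 settings their log2 fold changes stayed between 2.07 and 3.89. Limma's prior degrees of freedom were infinite with median centring, with the block and without either LPS array. A probe set's own spread did not count there, so calls in these fits are not comparable with those at the main prior of 9.87. Of the 14 lists, 5 passed again in the same direction with quantile normalization and 9 with median centring. Over 118 named genes and all alternatives, 0 values changed sign for genes called or at least 2-fold different in all 4 pairs. That selection itself makes a change of sign unlikely. Of other genes, 27 values changed sign, which is not counted as a reversal. Apart from fewer probe sets, pairs or arrays, the cause was not tested.

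The replicate numbers are shared by the groups, and no label says that a number stands for a day or culture. With the number as a block, limma called 671 probe sets, 404 higher and 267 lower, 391 genes, 224 higher and 167 lower, and 15 lists. With quantile normalization besides, it called 903 probe sets and 533 genes, 312 higher and 221 lower. Of the 14 lists, the block ended the call of the alternative activation markers (camera adjusted p = 0.0854). With quantile normalization besides, only 6 of the 14 passed in the same direction, the cytokine list among them (camera adjusted p = 0.00244). The differences between replicates 1 and 2 correlated between the groups at r = 0.38 over the tested probe sets.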

Other observations

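Tests of the shared cell preparation, of the other splits of the arrays, of the authors' scaling for the reference genes and for the lists, and of the array explanation for the Flcn and Fnip2 group and for the Rag GTPase list were chosen or reworded after the result was seen, and the filter at a mean signal of 500 was not planned. The 3 further gene lists were written after the first results were seen and before they were tested, and their p-values are adjusted over the 3. Genes named in this part were chosen after their values were seen.

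Outside the lists, several genes were at least 2-fold higher with immune complexes in all 4 array pairs without passing the test. Hilpda, a lipid droplet protein, had a log2 fold change of 2.29 (limma adjusted p = 0.0532) and Emp1, a membrane protein, 2.30 (0.0678). Cxcr4, the receptor of CXCL12, had 2.20, and Cd300lb, an activating myeloid receptor, 1.96. Bach1, a repressor of Hmox1, had 1.13, with readings of 7039.7 and 6424.5 with LPS and 15154.7 and 14382.6 with immune complexes.

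Flcn, Fnip2, Vps18, Wdr91 and Cln8 were at least 2-fold higher in all 4 array pairs, with log2 fold changes of 1.64, 1.76, 1.66, 1.53 and 2.12, none past the threshold. The probe sets that stand for Flcn and Cln8 have IDs ending in _x_at, so they can bind transcripts of other genes. Flcn and Fnip2 form a complex that controls Rag GTPases at the lysosome, and a hypothesis is that uptake of immune complexes may engage the transcription factors TFEB and TFE3, which induce such genes. For 30 tested lysosomal hydrolase and proton pump genes the median was -0.05 (95% bootstrap interval -0.16 to 0.08, limma camera adjusted p = 0.911). This argues against a general rise as large as that of the 5 genes. The intervals here resample genes and not arrays, so they leave out the spread between arrays. A smaller rise stays open, since the reference genes lay at -0.22 and the list was higher with quantile normalization (median 0.06, limma camera adjusted p = 0.00336). Of the proton pump genes in that list, Atp6v1a, Atp6v1d and Atp6v1c1 lay highest, at 0.71, 0.76 and 0.66. Atp6v0d2, Atp6v0d1, Atp6v1b2, Atp6v1e1 and Atp6ap1 lay at 0.51, 0.26, 0.11, 0.07 and -0.21. A list of 11 other genes, named for Rag GTPases and autophagy, had a median of 0.61 (0.08 to 0.69), with 10 of them above 0. Besides Rag GTPase and autophagy genes it held Gpnmb, Tfec and the proton pump gene Atp6v1h, whose own value of 0.61 set the median. The limma camera adjusted p of the list was 0.00268, and 0.22 with an estimated correlation. Fnip1 lay at 1.77 and Tfec, on the other side, at -0.91. With quantile normalization the 5 genes stayed at least 1.17 higher on the log2 scale in every array pair. They had been picked by a 2-fold rule in the same pairs, so this outcome was largely fixed. It cannot tell how far the raised low signals of the first LPS plus immune complexes array contributed. The level of the 5 genes argues against those low signals as the whole source of their rise. They read at least 1082.5 on that array, where the median of all signals was 155.8 and the 5th percentile 28.1. For the list those signals stay open. Its median was 0.49 (0.16 to 0.76, limma camera adjusted p = 8.14e-05) with that normalization but 0.39 (-0.18 to 0.65, 8 of 11 higher) in the replicate 2 pair of arrays. With 0 genes of the list past limma's threshold over all probe sets, the hypothesis of TFEB and TFE3 stays open as well.

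More probe sets differed between replicate numbers, 304, than between stimulations, 14, so 2 of the 3 splits of the 4 arrays gave at least 14, and 3 splits are too few for a share under 0.05. The highest of the other splits, 304, was the one by replicate number, which points to a structure of the samples. The raised low signals of the first LPS plus immune complexes array are argued against as the whole source, since 231 probe sets differed between replicate numbers among those with a mean signal of 500 or more. A candidate explanation is a cell preparation or processing day shared by arrays of the same number. Over those bright probe sets the replicate differences of the groups correlated at r = 0.67 across probe sets, which are not independent replicates. Calls between replicate numbers arise where these differences agree, so the correlation restates the calls and cannot decide between explanations. Cell cycle genes were higher in replicate 2 by medians of 1.77 in the LPS arrays and 1.85 in the others, with 16 of 18 higher in both. No label links a number to a preparation, so a shared preparation stays a hypothesis.

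Bright genes, the reference genes included, had slightly lower signals with immune complexes. The first LPS plus immune complexes array alone is argued against, since the reference gene median was -0.25 without it. A difference in signal distribution between arrays that the authors' scaling left in place may account for the reference genes, whose median went from -0.22 to -0.02 with quantile normalization. For the 10 lists called lower it stays open: 1, the NF-kB list, kept its call with that normalization, but 5 kept over 50% of their median, with -0.41 to -0.28 for NF-kB, -0.53 to -0.38 for cytokines, -0.30 to -0.21 for cholesterol synthesis, -0.21 to -0.19 for alternative activation and -0.18 to -0.12 for type I interferon. A biological shift of bright transcripts against dim ones was not tested and would be removed by the same normalization.

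Cipc, Cry1, Bhlhe40 and Usp2, which are tied to the circadian clock, had log2 fold changes of 2.60, 1.74, 2.03 and 1.68. Whether core clock genes may move with them was left undecided by a list of 12 other clock genes, with a median of 0.06 (95% bootstrap interval over genes -0.14 to 0.93) and limma camera adjusted p = 0.349. Its highest members, Nr1d1, Hlf and Bhlhe41, read 498.4, 263.1 and 360.2 on the first LPS plus immune complexes array, the one with raised low signals. On the second they read 15.1, 10.2 and 168, while Nr1d2, at 0.89, read 2157.2 and 1901.1 against 1379.9 and 838.8 with LPS. Among probe sets with a mean LPS signal over 500, 244 were at least 2-fold higher in the replicate 1 pair of arrays and 40.6% of these also in the replicate 2 pair, against 2% of all such probe sets. In the lower direction the numbers were 354, 18.4% and 1.2%. At a mean LPS signal of 100 to 500 they were 1633, 6.8% and 2.7% for higher and 616, 4.9% and 5.2% for lower probe sets, and under 100 they were 3561, 7.1% and 7.3% for higher and 42, 0% and 8.1% for lower ones. Under 100, the filter on mean signal lets no probe set be 2-fold lower in both pairs, so that 0% was fixed in advance. Probe sets this dim with LPS pass it more readily if their LPS plus immune complexes readings are high. The 2 directions therefore cannot be compared there.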
